A study of Mus musculus with 4 samples.

How the data were processed

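Gene expression was measured on 4 Affymetrix 3' expression arrays of 45101 probe sets. Per the labels, the cells were Lin-Sca-1+c-Kit+ (LSK) cells, a bone marrow fraction enriched for haematopoietic stem cells and early progenitors. They came from C57BL/6 mice that had been reconstituted with fetal liver cells, either necdin null or wild type, and had then received a sublethal dose of 6.5 Gy. Each of the 2 groups has 2 arrays. The time between irradiation and cell collection is not given in the sources used here. Nothing in the labels says that the replicates came from separate animals. P-values of single genes thus measure only the spread between these arrays, which may be technical in part. The sex-linked signals differed between the replicates of both groups, so the arrays of a group are not repeats of 1 RNA; whether each holds 1 animal or a pool is not given in the sources used here. The number of arrays limits the precision of each value.

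Per the labels' protocols, biotinylated cRNA was made from total RNA extracted with a column kit. Per the submitters' processing notes, the deposited intensity values are MAS5 signals; the version is not given in the sources used here. They are on a linear scale, and the mean after trimming 2% of the probe sets at each end is 500.004 on each of the 4 arrays. Detection calls were not used here.

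Probe sets were named through the platform annotation. Of the 45101 probe sets, 34958 had 1 gene symbol, 932 had several and 9211 had none in that table; only those with 1 symbol were named. Gene identifiers of 34754 probe sets were found in the RefSeq table of assembly GRCm38.p6, and 0 symbols needed a newer form. The files name no genome build, so no coordinates are given. The probe sets gave 18194 genes. A probe set without a name there is unnamed here, not without a gene; Bax was for this reason not analysed here.

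Values were analysed as log2(signal + 3.80), where the pseudocount is the 10th percentile of all values, so a log2 difference understates the change of low genes. No further normalization was applied. Each gene was represented by its probe set of highest mean log2 value, and genes at or above the 40th percentile of all probe sets (log2 value 5.09) were kept, which left 12680. Necdin null was compared with wild type with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05). Differences are necdin null minus wild type. An exact permutation test of 2 against 2 arrays cannot give a two-sided p below 0.333.

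Gene lists were fixed before the data were examined. There were 35, with 1042 of 1153 entries on the array, and the 34 with at least 5 measured members were tested with camera (limma, preset correlation 0.01). With a preset correlation, camera compares the members of a list with the other genes. Its p-values therefore do not measure the spread of a list between arrays. The lists on p53 target genes, pro-apoptotic genes, G2/M and mitosis genes and regulators of stem cell quiescence followed the question of the labels. The rule for named genes was also fixed before the data were examined: Ndn; genes past the threshold whose groups did not overlap, up to 10 per direction; where fewer passed, the genes of smallest moderated p among those with groups apart and at least a 2-fold difference, given as values that did not pass; in each list discussed, up to 4 members passing over the list alone or else the 2 of smallest p; members of the list of chromosomal neighbours of Ndn with an unadjusted p under 0.05, of which there were 0; and Cdkn1a, Mdm2, Bbc3 and Bax. Sex-linked genes are given per array. Lists not described singly are given by the range of their medians.

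The same code was tested on simulated arrays of 2 against 2, with 200 changed genes among about 12720 tested in each of 20 simulations. With variances drawn from limma's fitted prior, it called 4.12% of genes changed 2-fold, 55.6% of those changed 4-fold and 90.2% of those changed 16-fold; 6.04% of its calls were false, and 2 of 20 simulations without any change called a gene. A second version kept each probe set's moderated variance, shrunk by limma toward its prior, which departs from the model. It called 31.9%, 79.1% and 98.7% of genes changed 2-fold, 4-fold and 16-fold. In 12 of 20 simulations without change it called at least 1 gene, and 8.8% of calls were false. A list shifted by 0.5 on the log2 scale was called in 18 and 20 of 20 simulations respectively. Simulated genes were independent of each other, so the preset correlation was not tested by them.

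Alternatives fixed before the data were examined changed the pseudocount, the filter, the normalization between arrays, the variance model, the choice of probe sets, the set test and the calling threshold, added the replicate number as a block, or left out each array in turn. Each Ndn probe set on its own, quantile normalization together with the block, and an estimated correlation for the lists by replicate number and for the remaining division of the arrays, were added after seeing the data. Plots were drawn with matplotlib 3.10.9.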

Results

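The comparison asked how LSK cells lacking necdin, a growth-suppressing protein encoded by the imprinted gene Ndn, differ from wild type LSK cells in irradiated, reconstituted mice. It rests on 2 necdin null and 2 wild type arrays. The median signal was 61.3 and 62.4 on the necdin null arrays and 53.7 and 63.2 on the wild type arrays. Rank correlations between arrays, across probe sets, lay between 0.89 and 0.92, and pairs within a group (0.90 in both groups) lay within the range of pairs across groups.

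Ndn was lower in both necdin null arrays. The probe set of highest mean log2 value, 1437853_x_at, gave 80.2 ± 35.1 (SD, n = 2) in necdin null and 254.0 ± 2.08 (SD, n = 2) in wild type cells, a log2 difference of -1.68 with a standard error of 0.46. Other Ndn probe sets had low signals in necdin null cells: 1435383_x_at gave 1.74 and 4.86 against 504 and 329 in wild type, and 1435382_at gave 2.73 and 12.1 against 559 and 391.8. Of the 8 Ndn probe sets, 5 passed the filter on low values, and all 5 were lower in necdin null cells, with limma adjusted p between 0.00018 and 0.011 when adjusted over the 8 Ndn probe sets alone. None passed over all probe sets (adjusted p = 0.61 at the lowest). The 3 remaining probe sets had signals of at most 43.9. Which part of the gene was deleted is not given in the sources used here, so a probe set outside it would not check the genotype.

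**Figure D1:**
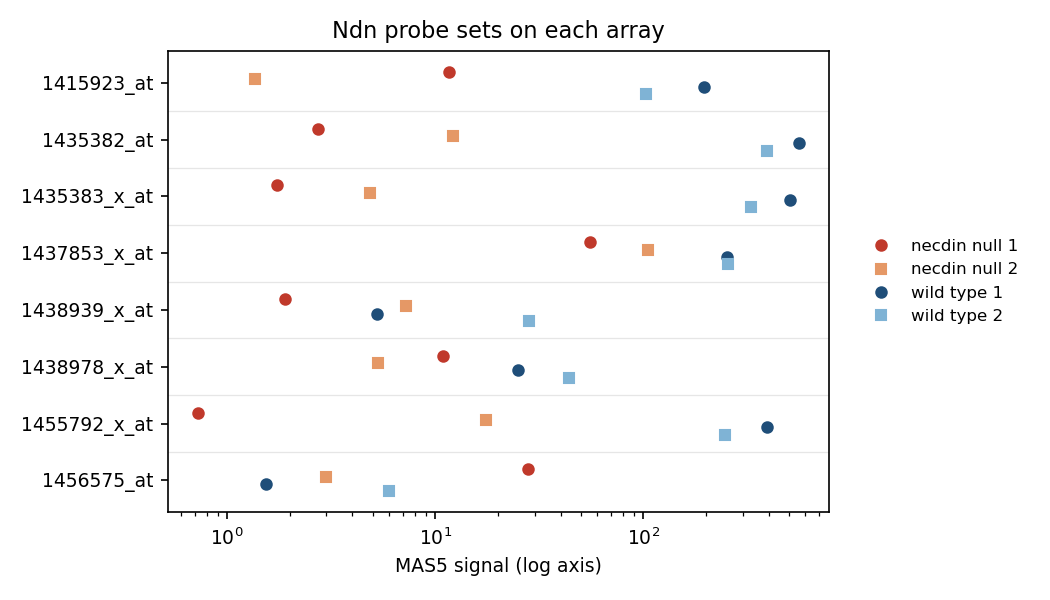
MAS5 signal (log axis) of each of the 8 Ndn probe sets on the 4 arrays; each point is 1 array. In 5 probe sets both wild type arrays lie above 100 and above both necdin null arrays, for example 504 and 329 against 1.74 and 4.86 for 1435383_x_at.

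No gene passed the threshold between necdin null and wild type cells. The genes with the smallest p that were higher in both necdin null arrays included Gas2l3, a cytoskeletal linker of dividing cells, at 2683 ± 271 against 893 ± 265 (SD, n = 2 each; log2 difference 1.61, standard error 0.24), and Xaf1, an interferon-inducible partner of the apoptosis inhibitor XIAP, at 1266 ± 14.5 against 474 ± 12.1 (1.41, standard error 0.22). Gclm, the modifier subunit of the enzyme that starts glutathione synthesis, had 2074 ± 177 against 1029 ± 0.35 (1.01, standard error 0.20). Among the lower genes, Ddit4, a stress-induced inhibitor of mTORC1, had 547 and 138 in necdin null against 1556 and 1187 in wild type cells (log2 difference -2.29, standard error 0.53). Tcl1b3, a member of the Tcl1 family, had 885 ± 18.8 against 3146 ± 1596 (-1.73, standard error 0.32).

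The other values higher in necdin null cells were those of Sema6c (log2 difference 2.26), 9530082P21Rik (2.93), 2610316D01Rik (3.70), Zfp934 (1.73), Vmn1r44 (2.61), Spef1 (3.02) and Ddx55 (2.38). Several of these had low wild type signals, such as 14.9 for Spef1 and 17.1 for Vmn1r44, and 2610316D01Rik had 266 and 2182 on the necdin null arrays. Lower values were found for Pdap1 (-1.03), Prcp (-1.03), Rrp1b (-1.13), Dubr (-2.33), Sel1l3 (-2.22), 6030498E09Rik (-1.98), Zfp516 (-1.44) and Gm3604 (-1.99). Probe sets above the filter did not all point the same way for Gas2l3 (2 of 3), Sema6c (1 of 2), Ddx55 (1 of 2), Prcp (2 of 4) and Rrp1b (2 of 3). The limma adjusted p of these 20 genes was 0.98 or higher.

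**Figure D2:**
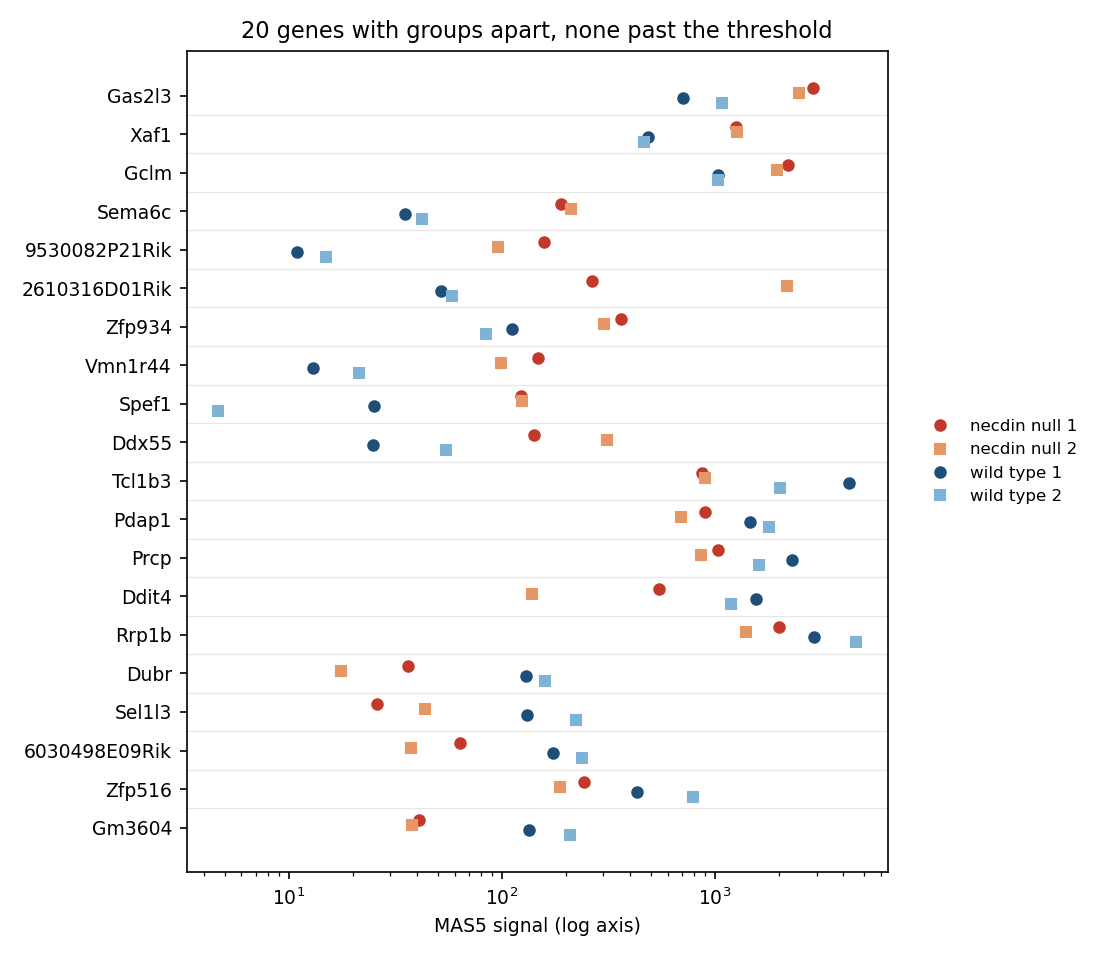
MAS5 signal (log axis) on the 4 arrays of the 20 genes named by the fixed rule; each point is 1 array. The groups lie apart by construction of the rule, and no gene passed the threshold; Gas2l3 lies at 2875 and 2491 in necdin null against 706 and 1081 in wild type.

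With limma, 0 of 12680 genes passed. With the replicate number added as a block 3 passed (Gas2l3, Tcl1b3 and Ddit4), and 0 with quantile normalization as well. At an unadjusted p under 0.05 there were 383 genes, 136 higher and 247 lower, where chance alone gives 634. With the replicate block there were 675. The groups did not overlap for 30.5% of genes (1617 higher, 2250 lower), against 33.3% by chance, and 393 of these differed at least 2-fold (189 higher, 204 lower). The balance of directions moved with the scaling, the probe sets and the arrays: median centring gave 941 higher and 2942 lower with groups apart, 86 and 331 at an unadjusted p under 0.05 and 146 and 279 by 2-fold difference with groups apart. By that last measure quantile normalization gave 150 and 251, and all probe sets 903 and 552. The 383 genes became 981 without necdin null replicate 1, 231 without necdin null replicate 2, 594 without wild type replicate 1 and 540 without wild type replicate 2, where the balance turned (315 higher, 225 lower; 556 and 312 by 2-fold difference with groups apart). In simulated arrays of this design, with variances drawn from limma's fitted prior, 4.12% of genes changed 2-fold and 55.6% of genes changed 4-fold were called. With each probe set's moderated variance these were 31.9% and 79.1%. Leaving out 1 array moved the count of called genes to 3 without necdin null replicate 1 (Xist, 2610316D01Rik and Ddit4), 2 without wild type replicate 1 (Ighg3 and Frmd4b) and 4 without wild type replicate 2 (Eif2s3y, Dhx36, Kdm5d and Tcl1b3), the lone array of a group being assumed to vary like the others. Of these, Xist, Eif2s3y and Kdm5d are sex-linked, and Ighg3, Frmd4b and Dhx36 are named after their values were seen.

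None of the 4 lists that follow the study's question was called, and no member passed, either over all genes or adjusted over the list alone. Among 43 p53 target genes, 24 were higher and 19 lower in necdin null cells, with a median log2 difference of 0.04 (camera adjusted p = 0.76). Ddit4l had 1.27 with a standard error of 0.58, and 1 of its 2 probe sets above the filter was higher. Its wild type signals were 27.0 and 31.2, near the filter at 30.3. Pltp had 0.76. Cdkn1a, the cell cycle inhibitor p21, had 0.33 with a standard error of 0.39, Mdm2, the negative regulator of p53, had -0.06 with a standard error of 0.22, and Bbc3, which encodes the pro-apoptotic protein PUMA, had -0.38 with a standard error of 0.38. Among 30 pro-apoptotic genes, 16 were higher and 14 lower, with a median of 0.03 (camera adjusted p = 0.61). Casp6 had 0.38 and Bcl2l11 0.52. Of the probe sets above the filter, 3 of 4 for Bcl2l11 and 1 of 2 for Mdm2 had the direction given.

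Among 57 G2/M and mitosis genes, 22 were higher and 35 lower, with a median of -0.05 (camera adjusted p = 0.61), which was -0.0025 without wild type replicate 1 and -0.13 without necdin null replicate 1 or wild type replicate 2. In this list 11 of 57 genes were lower and 1 was higher with groups apart. Over all 12680 genes 2250 were lower and 1617 higher with groups apart, so the lower share was near that of all genes. The higher share, 1 of 57, was below that of all genes. This imbalance was not tested. The proliferation marker Mki67 had 1271 ± 313 against 1981 ± 192 (SD, n = 2 each; log2 difference -0.66), and the cytokinesis regulator Racgap1 had 1428 ± 76.2 against 2042 ± 66.5 (-0.52). Among 39 regulators of stem cell quiescence, 18 were higher and 21 lower, with a median of -0.04 (adjusted p = 0.99); Foxo1 had -0.47 and Fhl1 -0.57.

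Of the 34 lists tested, 3 were called with the preset correlation, each higher in necdin null cells, and none with a correlation estimated from the data. The latter test had only 2 residual degrees of freedom and was adjusted over the 34 lists, so its lack of calls decides little. For the 3 called lists the estimates were 0.44 (neutrophil and granule), 0.23 (oxidative phosphorylation) and 0.70 (ribosomal protein). The calls with the preset of 0.01 thus rest on a correlation below these estimates. Neutrophil and granule genes had a median log2 difference of 0.36, with 21 of 25 members higher (camera adjusted p = 0.00092; adjusted p = 0.99 with an estimated correlation). No member passed adjusted over the list alone. Csf3r, the receptor for granulocyte colony-stimulating factor, had 0.41. The chemokine receptor Cxcr2 had 1.33 with a standard error of 0.76. Its signals of 153 and 222 in necdin null against 27.3 and 176 in wild type overlapped. For the list, the median deviation from the 4-array mean was -0.21 and 0.63 on the necdin null arrays. On the wild type arrays it was -0.47 and 0.32, so the groups overlapped. The median difference was 0.29 between the replicate 1 arrays and 0.33 between the replicate 2 arrays. Without necdin null replicate 2 it was -0.02, and without wild type replicate 1 it was -0.0036, and the call ended; without necdin null replicate 1 and wild type replicate 2 it was 0.66 and 0.67. In each case the remaining arrays are uneven in replicate number, by which this list differed by 0.72.

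Oxidative phosphorylation genes had a median of 0.17, with 34 of 43 higher (camera adjusted p = 0.0052; adjusted p = 0.99 with an estimated correlation), and ribosomal protein genes a median of 0.24, with 25 of 30 higher (adjusted p = 0.016; adjusted p = 0.99 with an estimated correlation). The members of smallest p went the other way or were small. Cox8a was at -0.43 (1 of 2 probe sets above the filter lower), Uqcrfs1 at 0.28, Rpl12 at -1.20 and Rpl37 at -0.36. Both calls ended with quantile normalization, at medians of 0.02 and -0.02, and with cyclic loess, at 0.06 each. Without necdin null replicate 2 the medians were -0.0039 and -0.11, the latter a call in the opposite direction (camera adjusted p = 0.0046), and without necdin null replicate 1 they were 0.31 and 0.62. The oxidative phosphorylation call also ended without wild type replicate 2 (0.12), and the ribosomal protein call without wild type replicate 1 (0.18) or wild type replicate 2 (0.29). The ribosomal protein call ended too without the filter on low values, without the intensity trend and with the replicate block (0.24 each). It also ended without _s_at, _x_at and _a_at probe sets (-0.06). Over the alternatives, the adjusted p of the ribosomal protein list ranged from 4.5e-29, without necdin null replicate 1, to 0.99. Necdin null replicate 2 also stood apart in its signs of RNA and array quality: its Gapdh 3' to 5' ratio was 15.8, against 10.96, 9.96 and 11.7 on the other arrays, and the brightest 1% of its probe sets held 37.4% of the signal, against 28.9% to 30.6%.

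**Figure D3:**
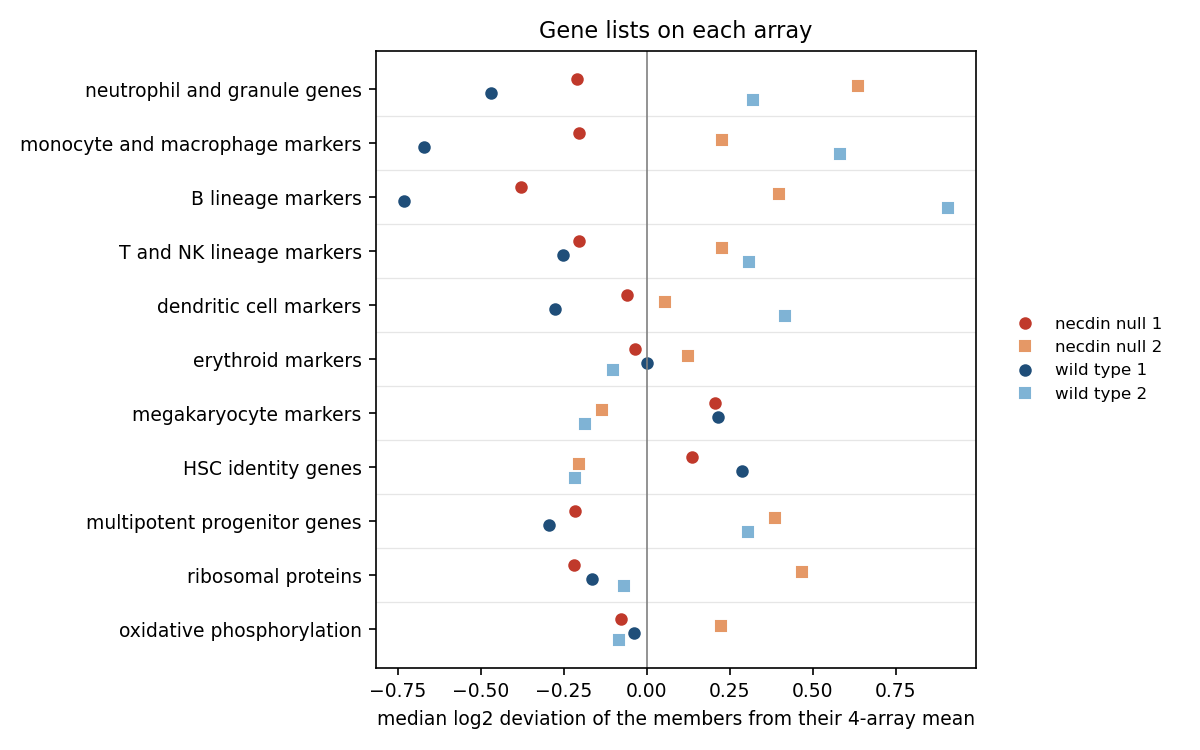
Median log2 deviation of the members of 11 gene lists from their 4-array mean; each point is 1 array. Ribosomal protein genes are high on necdin null replicate 2 alone (0.47, against -0.22, -0.17 and -0.07), while B lineage markers are high on both replicate 2 arrays (0.40 and 0.91).

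Type I interferon response genes were not called (median 0.09, 22 of 37 higher, camera adjusted p = 0.12), and 1 member passed adjusted over the list alone, Xaf1 (limma adjusted p = 0.0057), with 0 over all genes. Iigp1 had 0.59. Imprinted genes, the class to which Ndn belongs, were not called either (median 0.27, 13 of 18 higher, camera adjusted p = 0.12), and no member passed adjusted over the list alone. Ppp1r9a had 0.51 (2 of 3 probe sets above the filter higher) and Gatm 0.55. Both lists were called with a filter at the 60th percentile, at medians of 0.06 and 0.37. Without necdin null replicate 1 the interferon median was -0.016, and without wild type replicate 1 the imprinted median was 0.06. Chromosomal neighbours of Ndn had a median of -0.05, with 7 of 18 higher (camera adjusted p = 0.87), while their mean was 0.08 and the test pointed upward. Among the oxidative stress defence genes, Gclm passed adjusted over the list alone (limma adjusted p = 0.020), while the list had a median of -0.03 and was not called (camera adjusted p = 0.87, the test pointing upward). The 14 lists not described singly in this comparison were not called, with medians between -0.07 and 0.12 and camera adjusted p of 0.61 or higher, and for 7 of them the median, mean and test differed in sign.

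Markers of other cell types were called for the neutrophil list alone. Median log2 differences were 0.05 for erythroid, 0.02 for megakaryocyte, -0.06 for monocyte and macrophage, -0.12 for dendritic, -0.20 for B lineage, 0.05 for T and NK lineage, -0.28 for mast cell and basophil, -0.09 for endothelial and 0.14 for stromal and osteoblast markers. For the megakaryocyte and the T and NK lists the median and the mean differed in sign. The mast cell and basophil median was -0.02 with a filter at the 60th percentile and -0.04 without necdin null replicate 2. Without wild type replicate 1 the B lineage (-0.96) and the monocyte and macrophage list (-0.58) were called as lower, and without wild type replicate 2 both were called as higher (0.72 and 0.68). The B lineage list was also called as lower without necdin null replicate 2 (-0.56). Xist, transcribed from the inactive X chromosome, had 4841 and 76.8 on the necdin null arrays and 9930 and 7182 on the wild type arrays, and the Y-linked gene Eif2s3y had 2273 and 2987 against 32.6 and 1974. The Y-linked gene Kdm5d had 355 and 476 against 1.93 and 356. The sex-linked signals thus differed between arrays of the same group. Necdin null replicate 1 and wild type replicate 2 had high signals of both Xist and these Y-linked genes, so signals of both sexes were present there. Necdin null replicate 2 had high Y-linked signals with low Xist, and wild type replicate 1 the reverse. The source of these signals is not given in the sources used here.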

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

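The control transcripts, which take no part in the comparison of genes, were brighter on necdin null replicate 2 than on both wild type arrays. Hybridization controls added to the labelled cRNA (bioB, bioC, bioD and cre) had a geometric mean signal of 7197 there, against 4276 on necdin null replicate 1 and 4717 and 6328 on the wild type arrays. Controls of polyadenylated RNA (dap, lys, phe and thr) had 8869, against 4179, 4456 and 6841. Both replicate 2 arrays lay above both replicate 1 arrays.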

How the results depend on the processing

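Of the alternatives, each Ndn probe set on its own and quantile normalization with the replicate block were chosen after seeing the data. Ndn stayed lower under all of them except probe set 1456575_at, near background, at 1.02. The count of called genes, 0, stayed 0 under every change of pseudocount, filter, normalization, variance model or probe sets; it was 3 with the replicate block (Gas2l3, Tcl1b3 and Ddit4) but 0 with quantile normalization and the block (smallest adjusted p 0.39; genes at an unadjusted p under 0.05 were 675 with the block), 0 to 4 when leaving out 1 array, and 393 by a 2-fold difference with groups apart and no p-value. That count was itself 93 with the 60th percentile filter, 1462 without filter and 1455 over all probe sets. Replicate numbers were not treated as pairing in the main test. Deviations from group means correlated at 0.11 across genes, with only 2 pairs, which does not exclude a shared effect of the number. Divided by number, 1119 genes had an unadjusted limma p under 0.05, against 383 by genotype. Median centring moved the median of all genes from -0.03 to -0.11. The count of called lists was 5 with the 60th percentile filter, 1 with quantile normalization, cyclic loess or quantile normalization with the block, 0 with an estimated correlation or fry, and 2 to 5 when leaving out 1 array. Cell type lists called were 0 with an estimated correlation or fry, and 1 to 3 when leaving out 1 array. Those called were the neutrophil list without necdin null replicate 1 (0.66), the B lineage list without necdin null replicate 2 (-0.56), the B lineage (-0.96) and monocyte and macrophage lists (-0.58) without wild type replicate 1, and without wild type replicate 2 these 2 lists in the opposite direction (0.72 and 0.68) and the neutrophil list (0.67). Of the 14 lists not described singly, 2 were called in some setting, each when leaving out 1 array: stem cell identity (0.16 without wild type replicate 1, -0.43 without wild type replicate 2) and multipotent progenitor genes (0.45 without necdin null replicate 1, 0.39 without wild type replicate 2). The median of 13 of the 14 turned in some setting.

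Calls of oxidative phosphorylation ended at medians of 0.020 with quantile normalization (0.020 with the block too) and 0.062 with cyclic loess; those of ribosomal proteins at -0.018, -0.018, 0.058, and 0.24 without filter, without trend and with the replicate block, and -0.059 without _s_at, _x_at and _a_at probe sets. With an estimated correlation or fry the medians stayed at 0.17, 0.24 and 0.36 and the calls ended. Leaving out 1 array gave -0.0039 to 0.31 for oxidative phosphorylation, -0.11 to 0.62 for ribosomal proteins (called as lower at -0.11, without necdin null replicate 2), -0.022 to 0.67 for neutrophil genes, and -0.016 to 0.062 for interferon genes, which were called with the 60th percentile filter (0.060), as were imprinted genes (0.37; 0.063 to 0.36 when leaving out 1 array). The calls ended for oxidative phosphorylation without necdin null replicate 2 (-0.0039) and wild type replicate 2 (0.12), for ribosomal proteins without wild type replicate 1 (0.18) and wild type replicate 2 (0.29), and for neutrophil genes without necdin null replicate 2 (-0.022) and wild type replicate 1 (-0.0036). Leaving out 1 array also leaves the replicate numbers uneven. The neutrophil list was called with the replicate block (camera adjusted p = 3.7e-09, and 4.1e-09 with quantile normalization too), and its adjusted p over all alternatives ran from 2.3e-11, without wild type replicate 2, to 0.99. Among the 4 lists that follow the question, the direction turned for p53 targets with median centring (-0.046), for pro-apoptotic genes without filter (-0.018), with the 60th percentile filter (-0.038), median centring (-0.052) or all probe sets (-0.073), and for quiescence regulators without shared members (0.089). Leaving out 1 array gave -0.013 to 0.090, -0.0058 to 0.10 and -0.11 to 0.14 for these lists, and -0.13 to -0.0025 for G2/M and mitosis genes. Among other uncalled lists, the median turned for erythroid (-0.028), megakaryocyte (-0.065) and T and NK markers (-0.026) with median centring, for megakaryocyte markers also with pseudocount 1 (-0.036), without filter (-0.085) and without shared members (-0.036), for endothelial markers without filter (0.016), for stromal and osteoblast markers with the 60th percentile filter (-0.0092) and for oxidative stress defence without _s_at, _x_at and _a_at probe sets (0.051). Leaving out 1 array gave -0.064 to 0.19 for erythroid, -0.37 to 0.20 for megakaryocyte, -0.58 to 0.68 for monocyte and macrophage, -0.38 to 0.23 for dendritic, -0.96 to 0.72 for B lineage, -0.46 to 0.26 for T and NK, -0.18 to 0.18 for endothelial and -0.045 to 0.17 for stromal and osteoblast markers, -0.47 to -0.043 for mast cell and basophil markers (-0.024 with the 60th percentile filter), -0.081 to 0.12 for neighbours of Ndn and -0.044 to 0.077 for oxidative stress defence.

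The 20 genes of the comparison kept their direction in all 327 combinations of gene and setting. The rule took only genes with groups apart and at least a 2-fold difference. Leaving out 1 array therefore could not turn them, and their kept direction is no support for these genes. For 24 other genes, 12 of 401 combinations turned the direction. With all probe sets it turned for Pltp (-0.22), Bcl2l11 (-0.26) and Cdkn1a (-0.49). Without _s_at, _x_at and _a_at probe sets it turned for Bcl2l11 (-0.26) and Cox8a (0.23). With quantile normalization, with or without the block, it turned for Mdm2 (0.0065). Leaving out 1 array gave -0.011 to 1.06 for the gene Bcl2l11, -0.14 to 0.80 for the gene Cdkn1a, -0.20 to 0.079 for the gene Mdm2 and -0.45 to 4.77 for the gene Uty. The cause was not tested. Camera with an estimated correlation also rests on the 2 residual degrees of freedom, so calls can end without a higher correlation. For imprinted genes the estimate was -0.0095, below the preset 0.01, and the unadjusted camera p rose from 0.017 to 0.12. For the called lists the estimates lay above the preset, at 0.44 for neutrophil, 0.23 for oxidative phosphorylation and 0.70 for ribosomal protein genes. Their preset p-values thus rest on a correlation below the estimates, and a higher correlation may end these calls too. Signal over background limits genes such as Spef1, at 14.9 in wild type cells.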

Other observations

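The tests of explanations in this part were chosen after the results were seen, and leaving out each array was planned. With the arrays divided by number, 1119 genes had an unadjusted p under 0.05 and 10 lists were called, against 383 genes and 3 lists for the genotype and 339 genes and 3 lists for the remaining division of the 4 arrays into pairs. These lists were called with the preset correlation. With an estimated correlation 0 were called in each division (smallest camera adjusted p 0.55 by number, 0.99 by genotype and 0.96 for the remaining division). That test had only 2 residual degrees of freedom, so its 0 calls decide little. Multipotent progenitor genes were higher in both replicate 2 arrays by a median of 0.67 on the log2 scale, and genes of stem cell identity and megakaryocyte markers had -0.37 each. G2/M and mitosis genes had -0.17, and ribosomal protein genes 0.36.

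Lineage genes were higher in both replicate 2 arrays, by a median of 1.26 for B lineage, 1.00 for monocyte and macrophage, 0.72 for neutrophil, 0.59 for T and NK lineage and 0.46 for dendritic cell markers. The tables argue against array scale: the B lineage median lay at percentile 100 of 10000 lists matched on mean signal. Erythroid markers had a median of 0.077, below the lowest of those 5 lists. The standard error of 0.16 came from resampling the members and does not measure the spread between arrays. Within necdin null the erythroid median was 0.16, against 0.24 for dendritic cell markers. The erythroid values argue only weakly against a smaller share of the main cells that raises every other type alike. Megakaryocyte markers had -0.37 within necdin null and -0.47 within wild type, and mast cell and basophil markers had -0.25 and -0.21. Both lists were thus lower rather than raised. Whether the main cells express their members was not tested, so how far these lists argue against that explanation cannot be told. Control signals and RNA quality moved with the number too: on the replicate 2 arrays the hybridization controls were 1.68 and 1.34 times brighter and the polyadenylated controls 2.12 and 1.54 times in necdin null and wild type, and the Actb 3' to 5' ratio was 14.5 and 12.4 against 9.21 and 9.97. The gate excludes lineage-positive cells, and which of the remaining sources may apply stays open; the design gives no group for the number, so no biological explanation other than cell shares was tested.

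Neutrophil and granule genes had a median difference above 0, though the groups overlapped, with necdin null replicate 1 at -0.21 and wild type replicate 2 at 0.32. The call ended with an estimated correlation (camera adjusted p = 0.99). The median difference lay at percentile 100 of 10000 lists matched on mean signal, which argues against array scale as the whole cause. Mature granulocytes among the sorted cells, which the gate should remove, may contribute. Late granule genes exceeded progenitor granule genes by 0.25, but with a standard error of 0.17 this is too uncertain to decide. That standard error came from resampling the members and does not measure the spread between arrays. Of the 29 genes of the list, 25 were above the filter, progenitor genes such as Mpo among them. The abundant member S100a8 had 22732 and 55148 on the necdin null arrays and 14736 and 35494 on the wild type arrays, further apart between replicate numbers than between genotypes. Leaving out necdin null replicate 2 (-0.022) or wild type replicate 1 (-0.0036) decides nothing on whether 1 array accounts for the difference, since it leaves the replicate numbers uneven and the list differed by 0.72 between them; between arrays of the same number the median difference was 0.29 and 0.33. A difference due to the genotype stays open.

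Oxidative phosphorylation and ribosomal protein genes had median differences above 0, but only necdin null replicate 2 lay above both wild type arrays. Its median deviations were 0.22 and 0.47, against -0.08 and -0.22 on necdin null replicate 1. Both calls ended with an estimated correlation (camera adjusted p = 0.99). The oxidative phosphorylation median of 0.17 lay at percentile 97.86 of matched lists, whose own median was 0.11; the ribosomal protein median of 0.24 lay at percentile 99.98 of matched lists, with their median at 0.14, but was -0.02 after quantile normalization, so these values point apart, and a scale effect cannot be told apart from a change in these genes. That 1 array carries the difference goes with the value without necdin null replicate 2, -0.11, and that array's deviation of 0.47 was the only one above 0; between the replicate 1 arrays the median difference was -0.06, and between the replicate 2 arrays 0.55. The list differed by 0.36 between replicate numbers, by 0.67 within necdin null but 0.07 within wild type, whereas neutrophil genes differed by 0.79 and 0.76, so uneven numbers weigh less here. A single array may therefore be the source, and an effect of the genotype was not separable from it.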
